A study of Mus musculus with 12 samples.

How the data were processed

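RNA was measured in cultured mouse neural stem cells driven by PDGFB, a growth factor ligand used to model diffuse intrinsic pontine glioma, a childhood brainstem tumour. The cells expressed either wild-type histone H3.3 or H3.3 with the K27M substitution, in which lysine 27 of the histone tail is replaced by methionine. Each genotype received DMSO, the solvent, or 3 µM of EPZ6438, an inhibitor of the histone methyltransferase EZH2, for 12 days. The 12 libraries form 4 groups of 3 replicates. The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

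Per the labels' protocols, libraries were made from polyadenylated RNA with a TruSeq kit and sequenced on a HiSeq2500. Per the submitters' processing notes, reads were pseudo-aligned with kallisto and tested with sleuth, and the genome build is GRCm38 (mm10). Versions, the transcript annotation and the strand setting are not given in the sources used here. The authors deposited 4 tables, each for a pair of groups with 6 libraries. Per the file headers, each table gives estimated counts per transcript and library, a p-value and q-value per transcript, and an effect on the natural log scale with its standard error. The deposited estimated counts are divided by a size factor for each library, which was found from the values: the same library differed between tables by a constant factor over all transcripts. Low values of any transcript that occurred at least 5 times lay close to whole multiples of a step, and this step gave the factor. As a check, 47.1 to 62.2% of the low values of genes with a single transcript were then whole (tolerance 0.01). After the factors were undone, values of the same library in different tables differed by a relative 2e-09 at most. Every listed transcript had at least 5 counts in at least 3 libraries of its table, so transcripts below that level were not analysed here.

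Undone estimated counts were summed per gene and rounded to whole numbers. Transcripts with no gene name held 0.45 to 0.58% of the counts per library and stayed out of the tests. The tables listed 14040, 13643, 14442 and 13908 genes for K27M against wild-type H3.3 in DMSO, the inhibitor in wild-type cells, the inhibitor in K27M cells, and K27M against wild-type H3.3 under the inhibitor. Each pair of groups was tested on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM normalization, the quasi-likelihood test (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment, with a call at an adjusted p below 0.05. All tests were two-sided. Every adjusted p printed for a gene comes from this test unless another source is named. The difference of the inhibitor response between genotypes was the interaction term of the same model over all 12 libraries. It used the 34436 transcripts listed in all 4 tables (44294 are listed in any), which leaves out part of some genes' counts. Levels are normalized counts in CPM and are given as means ± SD over n = 3 libraries and are normalized within each fit, so the same group differs slightly between comparisons.

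Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 121 tests of lists with at least 3 measured members. Camera with a correlation estimated from the libraries, fry, and the percentile of each list's median among 10000 random lists matched on abundance were computed beside it. The 25 lists were PRC2 subunits, PRC1 subunits, H3.3 genes and chaperones, CDK inhibitors, p53 targets, mitosis, DNA replication, Hox genes, developmental transcription factors outside the neural lineage, cholesterol synthesis, interferon response, MHC class I presentation, germline genes, Wnt, BMP and Hedgehog ligands, hypoxia and glycolysis, unfolded protein and amino acid stress, and housekeeping genes, together with markers of neural stem cells, astrocytes, oligodendrocyte precursors, mature oligodendrocytes, neurons, microglia, endothelium, and mesenchymal cells. Counts adjusted over the list alone equal the counts over all tested genes unless they are given separately.

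The groups, tests, lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule names Ezh2, Suz12, Eed, Cdkn2a, Cdkn2b, Cdkn1a, H3f3a and H3f3b in each comparison, the 8 called genes with the largest rise and the 8 with the largest fall at or above the median abundance (6 each for the difference), and up to 4 members of a described list. It leaves out clone and model names and pseudogenes. A gene that the rule names for the inhibitor in wild-type cells is not reported here. The rule was written for transcripts that stand for their gene, and per-gene sums took their place because the tables hold counts. Corrections for GC content and transcript length, thinning of the libraries, the estimated correlation and fry were added after seeing the data. The GC correction removed each library's smooth trend of log expression with GC content (spline with 6 degrees of freedom, genes above a log2 CPM of 3, prior count of 2) as an offset. GC content, length and coordinates came from the GENCODE M21 annotation of GRCm38, which matched 43402 of 43794 transcripts and gave a length for 14548 of 14610 genes.

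Total estimated counts ranged from 7.9 to 24.09 M (megacounts) per library. Simulated changes were planted only in genes above the median abundance, and counts were drawn independently for each gene, without GC-linked deviations. Recovery in less abundant genes was not simulated. On simulated counts with the same depths, a planted change of 1.5-fold was recovered for 36 of 50 genes in K27M against wild-type H3.3 in DMSO, 36 of 50 for the inhibitor in wild-type cells, 50 of 50 for the inhibitor in K27M cells, 47 of 50 for the genotypes under the inhibitor and 30 of 50 for the difference. A group with 0 counts was given a floor of 3 counts over the group, and a group with 1 to 3 counts a ratio with an exact Clopper-Pearson interval of 95% confidence. Intervals and floors cover counting error only. Replicates were compared with a chi-square test of their counts over 8890 genes, and no pair lay within sampling noise. DESeq2 1.42.0 was run as an alternative, as were other thresholds and filters, the replicate number as a block, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

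H3f3a and H3f3b encode the same protein and have processed copies in the genome, and the introduced H3.3 sequence can share reads with them, so their values are uncertain. The transcripts of Cdkn2a share exons and the split between them is kallisto's estimate. As no strand setting is given, reads of overlapping and antisense genes cannot be told apart.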

Results

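The data are RNA-seq libraries of PDGFB-driven mouse neural stem cells that expressed wild-type or K27M histone H3.3, grown for 12 days with DMSO or with 3 µM of the EZH2 inhibitor EPZ6438 (n = 3 libraries in each of 4 groups). K27M H3.3 is the histone mutation of diffuse midline glioma, and EZH2 is the catalytic subunit of PRC2, the complex that methylates lysine 27 of histone H3 and represses developmental genes. Total estimated counts, in megacounts (M), were 13.35, 10.8 and 15.76 M in the wild-type DMSO libraries and 7.9, 13.56 and 8.71 M in the wild-type inhibitor libraries. They were 22.05, 23.07 and 24.09 M in the K27M DMSO libraries and 14.58, 12.41 and 10.89 M in the K27M inhibitor libraries. Wild-type DMSO replicate 1 stood apart from its group. Its counts differed from replicates 2 and 3 by a chi-square of 31.64 and 26.47 per gene, against 3.51 between replicates 2 and 3. Its deviations from the group mean followed GC content with a Spearman correlation of -0.80 across genes, which are not independent replicates. Replicates 2 and 3 had 0.69 and 0.65, as deviations from a group mean balance each other. In the other groups the correlations ran from -0.63 to 0.66, so GC-linked deviations were not particular to this library.

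K27M against wild-type H3.3 in DMSO asked how the mutant histone changed the cells without the inhibitor. Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf, was 4.19-fold lower in K27M cells, at 14.0 ± 0.555 CPM against 58.6 ± 3.58 CPM (SD, n = 3; log2 fold change -2.07, SE 0.068, adjusted p = 0.000155). The HoxA genes, which pattern the body axis, moved apart: Hoxa5 fell by 2.79 and Hoxa4 fell by 2.59 on the log2 scale, while Hoxa10 rose from 4 to 93 counts over the 3 libraries (log2 fold change 3.66, SE 0.654, adjusted p = 0.00542). Ezh2 rose 1.73-fold, from 113 ± 16.5 to 196 ± 4.47 CPM (adjusted p = 0.00197). In all, 3906 genes rose and 3991 fell among 13129 tested, and 878 rose and 155 fell at least 2-fold.

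Of the 11 measured PRC2 subunits, 8 rose and 0 fell (adjusted p = 0.0296; adjusted p = 0.574 with an estimated correlation). Suz12, a core scaffold of the complex, rose 2.38-fold, and Eed, which binds the methylated histone tail, 1.20-fold. With each library's GC trend removed the log2 fold change was 0.32 for Ezh2 (0.79 before), 0.57 for Suz12 and 0.11 for Eed. Eed then no longer passed (adjusted p = 0.118), and 4 members of the list rose and 1 fell. The Suz12 call was also lost without wild-type DMSO replicate 3 (adjusted p = 0.0675) or K27M DMSO replicate 1 or 2 (0.0568 and 0.0544). That of Eed was lost without any library but wild-type DMSO replicate 1 (highest adjusted p = 0.0778). Of 7 CDK inhibitors, which restrain the cell cycle, 2 rose and 2 fell (adjusted p = 0.422). Cdkn1c rose 2.23-fold and Cdkn1b 1.71-fold, while Cdkn1a, a p53 target, fell 1.37-fold alongside Cdkn2a. Cdkn1b stood at 0.31 and Cdkn1a at -0.21 on the log2 scale with the GC trend removed (0.77 and -0.45 before). Cdkn2b, the neighbour of Cdkn2a, had 12.3 ± 0.695 CPM in K27M and 13.3 ± 2.64 CPM in wild-type cells (adjusted p = 0.538). H3f3a and H3f3b had log2 fold changes of -0.06 (adjusted p = 0.429) and -0.08 (adjusted p = 0.0790). Without wild-type DMSO replicate 1 Cdkn2b and H3f3b passed, at -0.27 and -0.10 (adjusted p = 0.0222 and 0.00953).

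No lineage list passed in this comparison, although members moved in both directions. With the GC trend removed neural stem cell markers passed upward (9 rose and 2 fell, adjusted p = 0.0143), and astrocyte markers (4 and 8, adjusted p = 0.0162) and p53 targets (2 and 12, adjusted p = 0.00148) passed downward. Of 15 astrocyte markers, 4 rose and 8 fell (adjusted p = 0.0647). Gfap, the intermediate filament of astrocytes, rose 1.64-fold and the water channel gene Aqp4 3.02-fold, while the glycolytic enzyme gene Aldoc fell 2.49-fold and S100b 2.20-fold. Of 9 mature oligodendrocyte markers, 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0572): Ugt8a, an enzyme of myelin lipid synthesis, rose 6.12-fold and Tspan2 3.23-fold, and Cnp, a myelin enzyme, fell 1.63-fold. Among 12 oligodendrocyte precursor markers 2 rose and 7 fell (2 and 8 adjusted over the list alone; adjusted p = 0.160), including the proteoglycan gene Bcan, which fell 1.72-fold. Of 15 neuronal markers 3 rose and 2 fell (3 and 1 adjusted over the list alone; adjusted p = 0.358), with the neurofilament gene Nefm up 2.79-fold and Gap43 down 1.28-fold. Of 19 neural stem cell markers 6 rose and 3 fell (adjusted p = 0.664), with Lfng, a modifier of Notch receptors, down 1.49-fold. Of 7 Hox genes 2 rose and 3 fell (adjusted p = 0.0976), and of 9 developmental transcription factors outside the neural lineage 3 rose and 2 fell (adjusted p = 0.899; median log2 fold change -0.11 and mean -0.82, against an upward test direction). Pax9, a skeletal patterning factor, had 38 counts in wild-type and 0 in K27M cells, at least 21.9-fold lower, and the homeobox gene Prrx1 rose 2.10-fold. With the GC trend removed the log2 fold change was 1.04 for Tspan2, -0.43 for Cnp, -0.23 for Lfng and 0.46 for Prrx1 (1.69, -0.70, -0.58 and 1.07 before). Shh, the Hedgehog ligand, rose 2.24-fold and Wnt7a fell 1.88-fold in a list of 19 ligands and antagonists with 4 rises and 5 falls (adjusted p = 0.818).

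Leaving gene models without a name apart, the largest rises at or above the median abundance were in Col11a1, a fibrillar collagen gene (2.24, SE 0.169, adjusted p = 0.000558, log2 scale), the kinase gene Rps6ka6 (1.89, or 1.07 with the GC trend removed) and the adhesion gene Alcam (1.72). After Cdkn2a, the largest falls were in Gpd1, the glycerol phosphate dehydrogenase of the cytosol (-2.04, SE 0.075, adjusted p = 0.000209), the peroxidase gene Lpo (-1.61) and Psd (-1.34), with Timp4, an inhibitor of matrix metalloproteinases, further down the order (-1.22). The count of calls was 5105, 5092 and 5026 without wild-type DMSO replicate 3, K27M DMSO replicate 1 and K27M DMSO replicate 2. Fold changes ran with GC content (Spearman -0.78 across genes): the median log2 fold change was 0.86 in the decile of genes lowest in GC and -0.36 in the highest, and with the trend removed 2705 genes rose and 2911 fell, of which 3732 had the same call before.

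**Figure D1:**
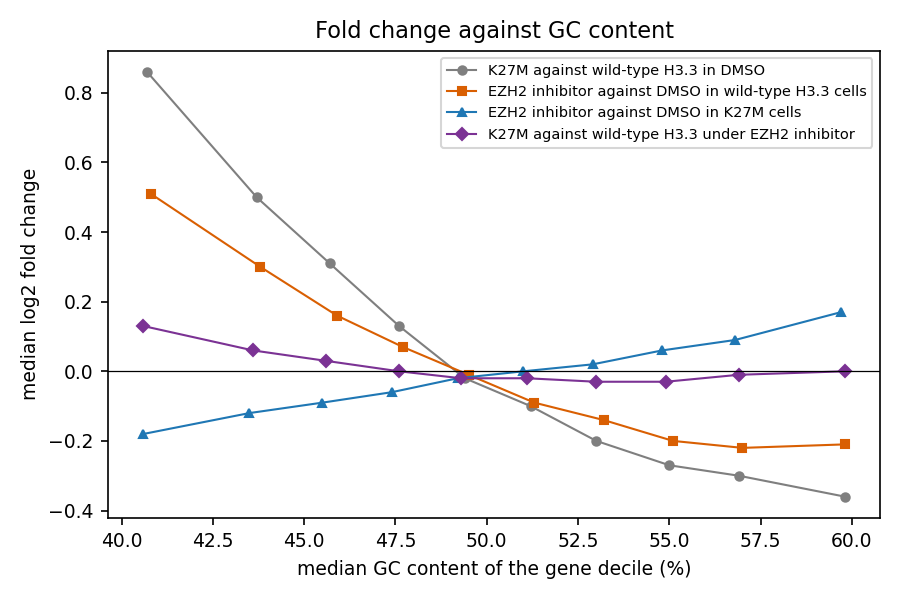
Median log2 fold change (vertical axis) of genes in deciles of GC content (horizontal axis, median % GC of the decile) for the 4 pairs of groups, each a line with a point per decile. In K27M against wild-type H3.3 in DMSO the medians run from 0.86 to -0.36, under the inhibitor from 0.13 to 0.00.

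EZH2 inhibitor against DMSO in wild-type H3.3 cells asked which genes respond to loss of EZH2 activity without the mutation. All 25 measured Hox genes rose, many from no detectable transcript: Hoxb8 had 0 counts in the 3 DMSO libraries and 20.7 ± 1.09 CPM under the inhibitor, at least 273-fold higher, and Hoxb3 rose at least 275-fold. Of the 25, 14 had 0 counts in DMSO. They were listed only through the inhibitor libraries, so they could only rise, and the list test includes them. Genes of other lists at 0 counts in DMSO could likewise only rise. Transcription factors of other tissues rose with the Hox genes, such as Twist1, a mesoderm factor with 1 count in DMSO and 948 under the inhibitor (ratio 1219, interval 218 to 48195), and Isl1, a motor neuron and heart factor that rose at least 84.4-fold. Cholesterol synthesis genes fell as a list, a call not kept with an estimated correlation (adjusted p = 0.305). Olig1, a factor of the oligodendrocyte lineage, fell from 2237 ± 169 to 468 ± 44.0 CPM (log2 fold change -2.26, SE 0.091, adjusted p = 1.50e-05). Cdkn2a rose 1.60-fold, from 59.7 ± 3.64 to 95.3 ± 10.8 CPM (adjusted p = 0.00204).

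The Hox list passed with adjusted p = 1.76e-58 (adjusted p = 0.0803 with an estimated correlation). Its median log2 fold change was 8.02, or 6.25 with genes absent in DMSO set to their bound. Of 33 developmental transcription factors outside the neural lineage, 31 rose and 0 fell (31 and 1 adjusted over the list alone; adjusted p = 3.11e-39, and adjusted p = 0.0767 with an estimated correlation). Of these 33, 9 had 0 counts in DMSO and could only rise. Of 20 neuronal markers 15 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 2.10e-08, and adjusted p = 0.0927 with an estimated correlation). Stmn2, a microtubule regulator of neurons, rose at least 114-fold and the glutamate transporter gene Slc17a6 at least 24.4-fold, while Gap43 of growing axons fell 2.30-fold. Of 14 mesenchymal and fibroblast markers 8 rose and 1 fell (adjusted p = 0.00240, and adjusted p = 0.572 with an estimated correlation). The matrix proteoglycan genes Dcn and Bgn were at least 48.9-fold and 28.7-fold higher. This list did not pass without wild-type DMSO replicate 1 (adjusted p = 0.0718).

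Of 20 p53 target genes 14 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 0.00377, and adjusted p = 0.199 with an estimated correlation). Perp, a desmosome and apoptosis gene, rose 3.86-fold and the apoptosis gene Pmaip1 2.73-fold, while the stress cytokine gene Gdf15 fell 4.58-fold. Of 7 CDK inhibitors 4 rose and 2 fell (adjusted p = 0.398): Cdkn1c rose by 2.32 on the log2 scale, Cdkn2b 1.46-fold and Cdkn1a 1.22-fold (log2 fold change 0.28, or 0.44 with the GC trend removed), and Cdkn2c fell 1.49-fold. The Cdkn2b call was lost without wild-type DMSO replicate 3 (adjusted p = 0.0864) or without inhibitor replicate 1, 2 or 3 (0.0578, 0.0749 and 0.119), and that of Cdkn1a without DMSO replicate 2 or 3 (0.0687 and 0.0889) or inhibitor replicate 2 or 3 (0.0703 and 0.0714). Of 20 DNA replication genes 14 fell and 0 rose (adjusted p = 0.00918, and adjusted p = 0.574 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell 1.44-fold. Of 20 mitosis genes 10 fell and 0 rose (adjusted p = 0.123, or 0.0249 with the GC trend removed), with the cyclin gene Ccnb2 down 2.15-fold.

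Of 20 cholesterol synthesis genes 17 fell and 0 rose (adjusted p = 2.14e-08, and adjusted p = 0.305 with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, fell 2.16-fold and Lss, lanosterol synthase, went from 341.9 ± 6.48 to 170.7 ± 8.75 CPM. Of 19 neural stem cell markers 2 rose and 12 fell (adjusted p = 0.00524, and adjusted p = 0.314 with an estimated correlation). Lfng fell 2.69-fold and Nr2e1, a receptor that maintains neural stem cells, 2.46-fold, while Prom1 rose 2.84-fold. Of 15 astrocyte markers 1 rose and 8 fell (adjusted p = 0.0156, and adjusted p = 0.224 with an estimated correlation). The folate enzyme gene Aldh1l1 fell 2.98-fold and the glutamate transporter gene Slc1a2 rose 2.08-fold. Of 12 oligodendrocyte precursor markers 1 rose and 4 fell (adjusted p = 0.0271, and adjusted p = 0.574 with an estimated correlation). Sox10, a factor of the same lineage as Olig1, fell 4.49-fold and the secreted protein gene C1ql1 rose 4.79-fold. Of 9 mature oligodendrocyte markers 2 rose and 2 fell (adjusted p = 0.927), with Ugt8a up 10.7-fold and the myelin gene Opalin down 16.5-fold. Of 11 PRC2 subunits 2 rose and 1 fell (adjusted p = 0.664): Jarid2, an accessory subunit, rose 1.61-fold and Phf19 fell 1.94-fold, while Ezh2, Suz12 and Eed had log2 fold changes of 0.25, 0.70 and 0.16 (adjusted p = 0.0913, 0.139 and 0.178). With the GC trend removed Ezh2 stood at -0.05 and Suz12 at 0.28. Without wild-type DMSO replicate 1 Ezh2 and Suz12 passed, at 0.33 and 1.15 (adjusted p = 0.00402 and 0.00289). Of 19 PRC1 subunits 5 rose and 1 fell (5 and 0 adjusted over the list alone; adjusted p = 0.333), with Pcgf2 up 4.07-fold. H3f3a had a log2 fold change of 0.23 (adjusted p = 0.117; 0.34 and adjusted p = 0.0244 without inhibitor replicate 1), and H3f3b rose by 0.42, a value of -0.02 with the GC trend removed.

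The largest rises at or above the median abundance were in St8sia2, which makes polysialic acid (3.92, SE 0.097, adjusted p = 4.59e-06, log2 scale), Pcolce, an enhancer of collagen processing (3.49), and the protease gene Pcsk5 (2.77), and the largest falls included Car8 (-3.22, SE 0.148, adjusted p = 2.06e-05) and the iron carrier gene Trf (-2.77). In all, 2752 genes rose and 2668 fell among 12870 tested (954 and 320 at least 2-fold; 2403 and 3091 with effects centred on the median), with 3344 calls without wild-type DMSO replicate 3 and 3425 without wild-type inhibitor replicate 3. Fold changes ran with GC content (Spearman -0.52 across genes).

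EZH2 inhibitor against DMSO in K27M cells asked the same question in mutant cells. All 27 measured Hox genes rose, with Hoxb8 and Hoxb9 at 0 counts in DMSO and at least 575-fold and 490-fold higher under the inhibitor, where they reached 25.4 ± 2.51 and 21.6 ± 0.904 CPM. Of the 27, 9 had 0 counts in DMSO, were listed only through the inhibitor libraries and could only rise. Cdkn2a rose 6.27-fold, from 14.2 ± 0.628 to 89.0 ± 5.95 CPM (log2 fold change 2.65, SE 0.064, adjusted p = 1.60e-09), and Cdkn1a 1.90-fold, from 279 ± 3.06 to 529 ± 7.93 CPM. Of 20 p53 target genes 18 rose, while 19 of 20 mitosis genes and 19 of 20 cholesterol synthesis genes fell. Egfr, the receptor of a growth factor in the culture medium, fell 3.07-fold and Ednrb, an endothelin receptor of glial progenitors, 4.39-fold (adjusted p = 4.67e-10).

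The Hox list passed with adjusted p = 6.10e-46 and adjusted p = 0.0383 with an estimated correlation, with a median log2 fold change of 6.91, or 6.24 with absent genes at their bound. Of 38 developmental transcription factors outside the neural lineage 36 rose and 0 fell (37 and 0 adjusted over the list alone; adjusted p = 1.15e-28, and adjusted p = 0.0383 with an estimated correlation). Of these 38, 11 had 0 counts in DMSO and could only rise. Alx1, a craniofacial factor, rose at least 248-fold and Isl1 at least 173-fold. Of 22 neuronal markers 17 rose and 3 fell (adjusted p = 5.41e-08, and adjusted p = 0.0803 with an estimated correlation): Neurod1, a neurogenic factor, rose 112-fold from 11 to 727 counts over the group, and Gap43 fell 1.65-fold. Of 16 mesenchymal and fibroblast markers 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000294, and adjusted p = 0.215 with an estimated correlation), with the collagen gene Col3a1 up 248-fold from 4 to 622 counts.

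The p53 target list (18 rose, 2 fell) passed with adjusted p = 9.84e-12 and adjusted p = 0.0426 with an estimated correlation. The death receptor gene Tnfrsf10b rose 2.66-fold and the apoptosis gene Bbc3 2.19-fold, while Gdf15 fell 1.93-fold and the stress gene Sesn1 1.77-fold. Of 7 CDK inhibitors 4 rose and 3 fell (adjusted p = 0.154), with Cdkn2b up 1.28-fold, Cdkn2c down 1.66-fold and Cdkn1b down 1.51-fold. The mitosis list (0 rose, 19 fell) passed with adjusted p = 2.42e-05 (adjusted p = 0.215 with an estimated correlation), with Ccnb2 down 2.62-fold and the proliferation marker Mki67 1.45-fold. Of 20 DNA replication genes 2 rose and 16 fell (adjusted p = 0.00131, and adjusted p = 0.171 with an estimated correlation), with Rrm2 down 1.54-fold and Rrm1 1.42-fold. The cholesterol synthesis list (0 rose, 19 fell, or 1 and 19 adjusted over the list alone) passed with adjusted p = 7.44e-19 (adjusted p = 0.0767 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from 1987 ± 28.5 to 835 ± 29.2 CPM.

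Of 19 neural stem cell markers 4 rose and 11 fell (5 and 11 adjusted over the list alone; adjusted p = 1.18e-07, and adjusted p = 0.215 with an estimated correlation). Egfr and Cd9 fell and Prom1 rose 2.14-fold. Of 15 astrocyte markers 5 rose and 9 fell (adjusted p = 0.000930, and adjusted p = 0.171 with an estimated correlation), with Aqp4 down 5.15-fold and Slc1a2 up 2.67-fold. Of 12 oligodendrocyte precursor markers 5 rose and 6 fell (adjusted p = 0.0892, or 0.00290 downward with the GC trend removed). Sox10 fell 10.7-fold and Gpr17, a receptor of differentiating precursors, fell by 3.32 on the log2 scale, while C1ql1 rose 5.89-fold. Of 10 mature oligodendrocyte markers 3 rose and 7 fell (adjusted p = 0.0963). Of 11 PRC2 subunits 2 rose and 5 fell (adjusted p = 0.253): Ezh2 fell 1.31-fold (adjusted p = 5.59e-05), Suz12 1.22-fold and Phf19 1.82-fold, Phf1 rose 1.48-fold, and Eed had a log2 fold change of 0.07 (adjusted p = 0.332). Suz12 stood at -0.14 and Phf1 at 0.37 with the GC trend removed (-0.28 and 0.56 before). The Suz12 call was lost without K27M DMSO replicate 1 or 2 or inhibitor replicate 3 (adjusted p = 0.0851, 0.0680 and 0.0561). H3f3a and H3f3b rose 1.20-fold and 1.23-fold.

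The other lists did not pass in K27M cells. Of 4 endothelial markers 2 rose and 1 fell (adjusted p = 0.264), the rises being the VEGF receptor genes Flt1, 5.34-fold, and Kdr, 2.38-fold. Of 21 ligands and antagonists of Wnt, BMP and Hedgehog signalling 7 rose and 9 fell (adjusted p = 0.429; median 0.00 and mean 0.37, against a downward test direction), with Shh down 3.06-fold and Wnt4 4.12-fold. Interferon response genes had 1 rise and 9 falls of 14 (2 and 9 adjusted over the list alone; adjusted p = 0.184), and genes of MHC class I presentation 2 and 5 of 12 (adjusted p = 0.805; median 0.03 and mean -0.04). Of 9 H3.3 genes and chaperones 2 rose and 1 fell (adjusted p = 0.753), of 4 microglia markers 2 and 1 (adjusted p = 0.927), and of 4 germline genes 0 and 2 (adjusted p = 0.381). Hypoxia and glycolysis genes had 3 rises and 8 falls of 18 (4 and 8 adjusted over the list alone; adjusted p = 0.398), unfolded protein and amino acid stress genes 8 and 6 of 20 (9 and 6 adjusted over the list alone; adjusted p = 0.899), and housekeeping genes 3 and 9 of 15 (adjusted p = 0.326).

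The largest rises at or above the median abundance were in the integrin gene Itga9 (3.84, SE 0.095, adjusted p = 1.70e-09, log2 scale), Pcolce (3.58) and Pcsk5 (3.13), and the largest falls in Car8 (-3.53, SE 0.054, adjusted p = 1.31e-10), Car3 (-3.16) and Nebl (-2.61). In all, 3908 genes rose and 3691 fell among 13503 tested (918 and 330 at least 2-fold; 3798 and 3831 with effects centred on the median), with a Spearman correlation of fold change with GC content of 0.33 across genes.

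**Figure D2:**
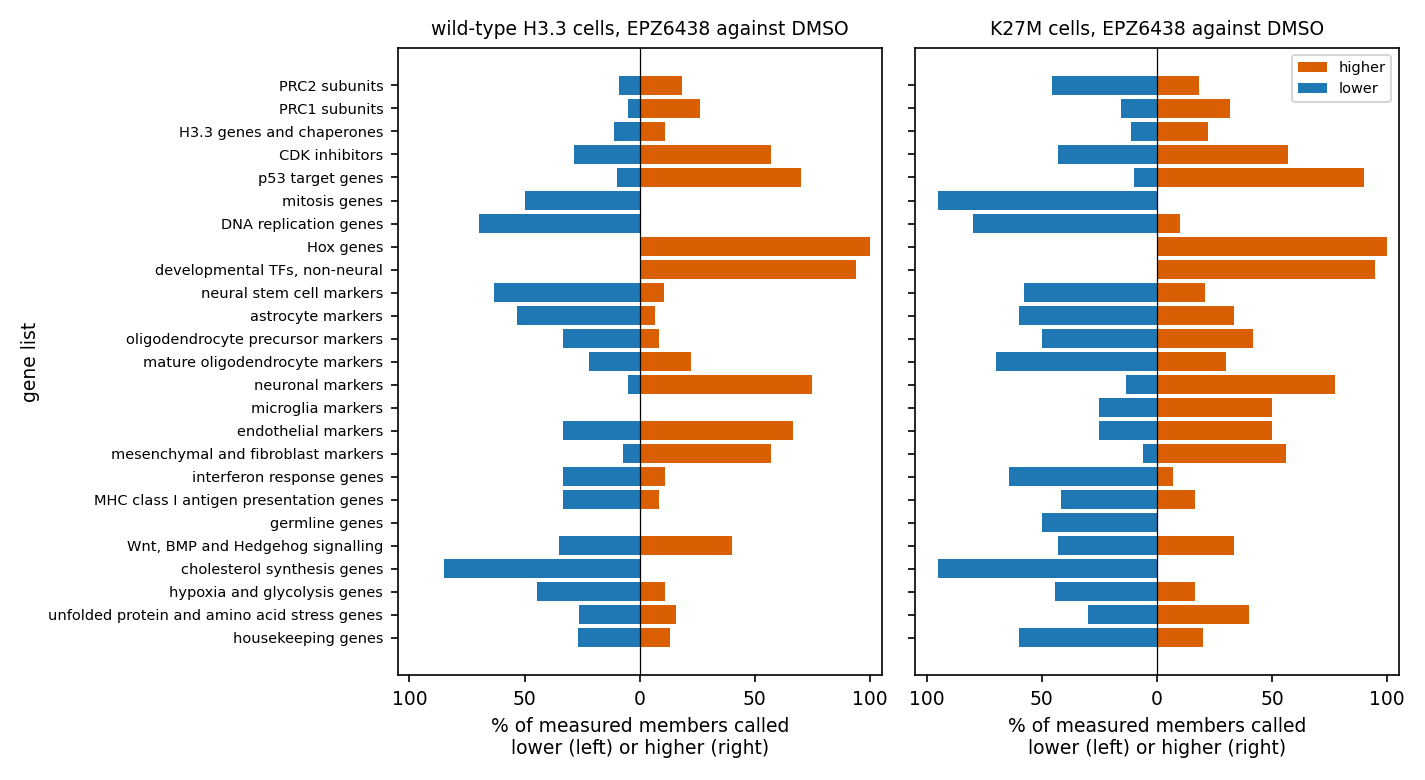
Share of each gene list's measured members (horizontal axis, %) called higher (right, orange) or lower (left, blue) under the inhibitor in wild-type H3.3 cells (left panel) and K27M cells (right panel). All measured Hox genes rose in both genotypes, including 14 in wild-type and 9 in K27M cells that had 0 counts in DMSO and could only rise. In K27M cells 19 of 20 mitosis genes fell. Microglia and germline lists had too few measured members in wild-type cells to be tested and have no bar there.

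K27M against wild-type H3.3 under EZH2 inhibitor asked what remained of the genotype difference once EZH2 was inhibited in both. The remaining differences were small and included astrocyte genes: 6 of 15 astrocyte markers fell in K27M cells and 0 rose (0 and 10 adjusted over the list alone; adjusted p = 6.54e-15, and adjusted p = 0.0383 with an estimated correlation). Gfap fell from 45.3 ± 1.46 to 26.2 ± 2.51 CPM (log2 fold change -0.79, SE 0.083, adjusted p = 0.00653) and Aldoc 1.49-fold. Hes5, a Notch target that maintains progenitors, fell 1.79-fold. Cdkn2a stood at 90.5 ± 6.21 CPM in K27M and 96.4 ± 9.95 CPM in wild-type cells, a difference that did not pass the test (log2 fold change -0.10, SE 0.085, adjusted p = 0.608). In all, 74 genes rose and 160 fell among 13060 tested, 234 calls, or 308 and 419 with the GC trend removed. With the replicate number as a block more genes were called, as given with the other settings below.

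The largest falls at or above the median abundance included the GABA transporter gene Slc6a11 (-0.84, SE 0.055, adjusted p = 0.00123, log2 scale), Mmd2 (-0.81), the Wnt inhibitor gene Apcdd1 (-0.77), Cntn1, an adhesion gene (-0.75), Ndrg2 (-0.73), Ttyh1 (-0.73) and the potassium channel gene Kcnj10 (-0.67). The Cntn1 call was lost without wild-type replicate 1 or 3 or K27M replicate 1, 2 or 3 (adjusted p = 0.0537, 0.123, 0.0760, 0.136 and 0.150). The largest rises included Sel1l3 (0.54, adjusted p = 0.00764), lost without K27M inhibitor replicate 3 (adjusted p = 0.0743), and the p53-induced gene Trp53i11 (0.44), lost without wild-type replicate 3 or K27M replicate 3 (adjusted p = 0.0626 and 0.0682). Of 11 oligodendrocyte precursor markers 2 fell and 0 rose (0 and 3 adjusted over the list alone; adjusted p = 0.000206, and adjusted p = 0.314 with an estimated correlation). Gpr17 fell 3.39-fold, a call lost without wild-type replicate 3 (adjusted p = 0.0505), K27M replicate 2 (0.0558) or K27M replicate 3 (0.0773). The other called precursor marker, Pdgfra, lost its call when any single library was left out (adjusted p up to 0.171). Of 20 p53 target genes 2 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.215 with an estimated correlation). Btg2, an antiproliferative gene, was the member that fell (1.37-fold).

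Further lists passed with few called members. With the GC trend removed the Hox list did not pass (adjusted p = 0.206), while mitosis genes (adjusted p = 0.0248) and hypoxia and glycolysis genes (adjusted p = 0.0380) passed upward. Unfolded protein and amino acid stress genes had 1 rise and 0 falls of 19 (2 and 0 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.292 with an estimated correlation; adjusted p = 0.0793 without wild-type replicate 3). Neural stem cell markers had 1 rise and 2 falls of 19 (2 and 6 adjusted over the list alone; adjusted p = 0.0271, and adjusted p = 0.486 with an estimated correlation). Mature oligodendrocyte markers had 0 rises and 1 fall of 8 (0 and 2 adjusted over the list alone; adjusted p = 0.0434, and adjusted p = 0.433 with an estimated correlation). The gene that fell, Cnp, lost its call when any single library was left out (adjusted p up to 0.172). Hox genes had 1 rise, Hoxb9, and 2 falls, Hoxd9 and Hoxa10, of 25 (3 and 6 adjusted over the list alone; adjusted p = 0.0482, and adjusted p = 0.574 with an estimated correlation). The gene calls of Hoxb9 and Hoxd9 were lost without any of the 6 libraries (adjusted p up to 0.171), and that of Hoxa10 without any but wild-type replicate 1 (up to 0.184). The neural stem cell list did not pass without wild-type replicate 2 or 3 or K27M replicate 1 or 3 (adjusted p = 0.0756, 0.0676, 0.0975 and 0.0556), the mature oligodendrocyte list without wild-type replicate 1 or 3 or K27M replicate 2 (0.0939, 0.226 and 0.305), and the Hox list without wild-type replicate 2 or 3 or K27M replicate 1 or 3 (0.430, 0.0934, 0.128 and 0.0656).

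None of the 7 CDK inhibitors was called (1 and 0 adjusted over the list alone; adjusted p = 0.398), with Cdkn1a at a log2 fold change of 0.18 (adjusted p = 0.124, or 0.0213 without wild-type replicate 2) and Cdkn2b at -0.31 (adjusted p = 0.186). None of the 11 PRC2 subunits was called (adjusted p = 0.381), with Ezh2 at 0.15 (adjusted p = 0.264), Suz12 at 0.26 (0.475) and Eed at 0.20 (0.239). Of 22 neuronal markers 0 were called (adjusted p = 0.899). H3f3a stood at -0.04 (adjusted p = 0.858), and H3f3b fell by 0.20, a call lost without any of the 6 libraries (adjusted p up to 0.221). The count of calls was 123 without wild-type replicate 1, 30 without wild-type replicate 3, and 32, 31 and 17 without K27M replicates 1, 2 and 3, of the inhibitor libraries. Of the genes tested in both genotype comparisons 27 rose and 82 fell in both, where independent lists would share 20.8 and 48.4 (Fisher's exact p = 0.0700 and 1.44e-08). Another 56 were called in opposite directions. With GC trends removed 127 rose and 207 fell in both, against 62.1 and 92.9 (Fisher's exact p = 6.87e-18 and 4.78e-36), and 128 were opposite. Genes are not independent replicates, so these Fisher p-values do not measure the spread between libraries. The SD of log2 fold changes was 0.587 in DMSO and 0.241 under the inhibitor, or 0.441 and 0.236 with GC trends removed.

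The difference of the inhibitor response between K27M and wild-type cells was tested directly. Cdkn2a responded more strongly in K27M cells, by 2.01 on the log2 scale (SE 0.119, adjusted p = 3.21e-06), as did Cdkn1a by 0.68 (0.42 with the GC trend removed). In group means Cdkn2a went from 60.8 ± 4.89 to 95.1 ± 9.29 CPM in wild-type and from 14.1 ± 0.583 to 89.2 ± 5.2 CPM in K27M cells. Hoxa5 and Hoxa4 responded more strongly in K27M cells by 2.74 and 2.40, while Gfap responded lower by -1.48 (SE 0.109, adjusted p = 1.35e-05): it stayed at 43.8 ± 3.27 and 44.5 ± 1.89 CPM in wild-type and went from 69.8 ± 1.98 to 25.5 ± 2.45 CPM in K27M cells. Of 13040 genes 2606 responded more in the upward direction in K27M cells and 2056 less, while at least 2-fold differences were 160 higher and 391 lower. By construction the difference is also the genotype effect under the inhibitor minus that in DMSO. As genotype effects under the inhibitor were small, much of it restates the DMSO difference between genotypes with its sign turned.

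Of 11 PRC2 subunits 4 responded lower in K27M cells and 0 higher (adjusted p = 0.0249, and adjusted p = 0.314 with an estimated correlation; adjusted p = 0.111 with the GC trend removed), Ezh2 by -0.62 (-0.23 with the GC trend removed) and Jarid2 by -0.72. Suz12 had a difference of -0.97 (-0.38 with the GC trend removed; adjusted p = 0.0657, or 0.000474 without wild-type DMSO replicate 1 and 0.0449 without wild-type inhibitor replicate 2) and Eed of -0.06 (adjusted p = 0.648). Of 8 mature oligodendrocyte markers 1 responded higher and 3 lower (adjusted p = 0.0296, and adjusted p = 0.239 with an estimated correlation; adjusted p = 0.0553 with the GC trend removed and 0.295 without wild-type DMSO replicate 1), Ugt8a by -2.65. Of 20 p53 target genes 9 responded higher and 3 lower (10 and 3 adjusted over the list alone; adjusted p = 0.0515). With the GC trend removed this list passed upward (adjusted p = 5.96e-08) and neural stem cell markers passed downward (adjusted p = 5.40e-05, against 0.324 before). Hox genes had 3 higher and 2 lower of 7 (3 and 3 adjusted over the list alone; adjusted p = 0.189; median 0.28 and mean -0.32) and CDK inhibitors 2 and 2 of 7 (adjusted p = 0.78; median -0.12 and mean 0.05), with Cdkn2b at -0.15 (adjusted p = 0.568). Astrocyte markers had 4 higher and 4 lower of 15 (adjusted p = 0.895; median 0.22 and mean -0.07). H3f3a and H3f3b had differences of 0.06 and -0.08 (adjusted p = 0.724 and 0.317), and H3f3b 0.48 with the GC trend removed (adjusted p = 0.0956). The differences ran with GC content (Spearman 0.77 across genes), and with the trend removed 1445 genes responded higher and 1366 lower, of which 1892 had the same call before.

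The authors' deposited table separates the products of Cdkn2a, which lies on the minus strand of chromosome 4 from 89274471 to 89294653 (GRCm38; gene ENSMUSG00000044303). The p16Ink4a transcript spans 89274471 to 89282192 and the p19Arf transcript, with its own first exon, 89274541 to 89294653. In the authors' deposited table p16Ink4a had a log2 effect of -3.91 for K27M in DMSO (SE 0.43, q = 2.84e-17), 1.34 for the inhibitor in wild-type cells (q = 2.37e-12), 5.05 for the inhibitor in K27M cells (q = 1.21e-47) and -0.20 between genotypes under the inhibitor (q = 1). In the authors' deposited table p19Arf had -1.80 (q = 1.47e-46), 0.21 (q = 0.493), 1.97 (q = 5.18e-88) and -0.04 (q = 1). Mean levels of p16Ink4a were 15.1 ± 3.01 CPM in wild-type DMSO, 41.2 ± 2.93 in wild-type inhibitor, 1.03 ± 0.31 in K27M DMSO and 36.2 ± 5.43 in K27M inhibitor libraries, and those of p19Arf 43.3 ± 1.09, 54.8 ± 8.31, 12.8 ± 0.61 and 53.5 ± 4.06 CPM. Over all transcripts the authors' deposited tables called 3021 higher and 3398 lower for K27M in DMSO, 1612 and 2330 for the inhibitor in wild-type cells, 2435 and 3253 for the inhibitor in K27M cells, and 38 and 145 between genotypes under the inhibitor. Their median effect in K27M against wild-type H3.3 in DMSO was 0.106 on the log2 scale, and with effects centred on the median the splits were 2312 and 4681 for K27M in DMSO, 1580 and 2423 for the inhibitor in wild-type cells, and 29 and 249 between genotypes under the inhibitor.

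**Figure D3:**
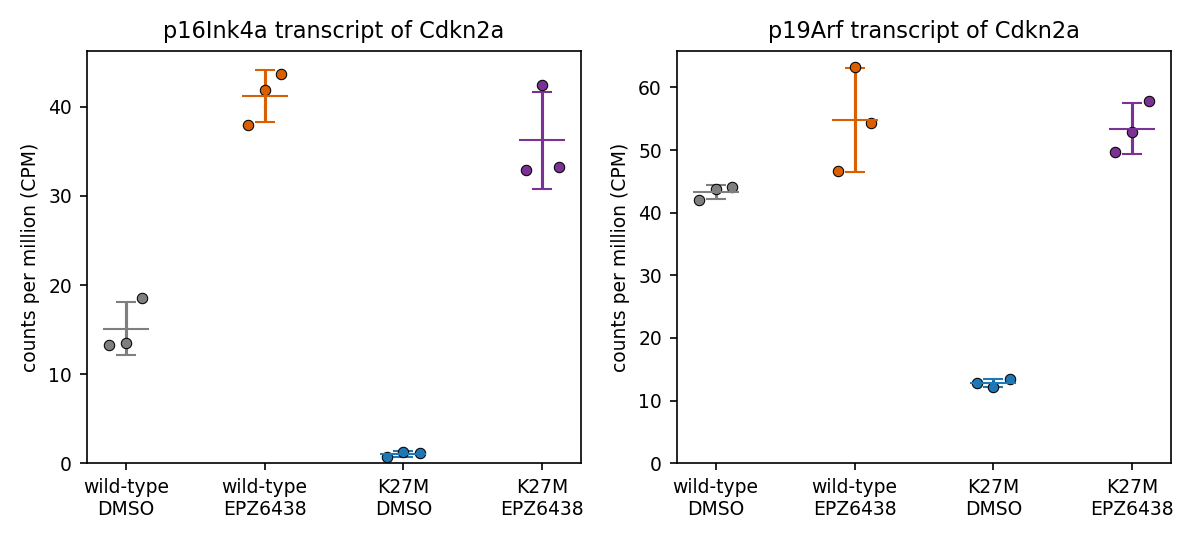
Levels in CPM (vertical axis, from 0) of the p16Ink4a (left) and p19Arf (right) transcripts of Cdkn2a in the 4 groups, with a point per library and the mean ± SD (n = 3). The K27M DMSO libraries lie lowest for both transcripts, at means of 1.03 and 12.8 CPM.

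The inhibitor responses of the genotypes overlapped. Among 12836 genes tested in both, 1712 rose in both and 1526 fell in both, where independent lists would share 803 and 754, and 463 were called in opposite directions. With GC trends removed 2196 rose and 2125 fell in both, and 283 were opposite. The fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.801, and these comparisons share no libraries. Both r and the shared rises include genes with 0 counts in DMSO, which were listed only through the inhibitor libraries and could only rise. The SD of the wild-type inhibitor effects was 1.006 over the 12836 genes. It was 0.724 over the 12660 genes also tested in K27M against wild-type H3.3 in DMSO. An r without genes that could only rise was not computed. Members called over all tested genes rose in the Hox and developmental transcription factor lists and fell in the cholesterol synthesis list, in both genotypes. The size of the response differed between genotypes for some members, such as Hoxa5.

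**Figure D4:**
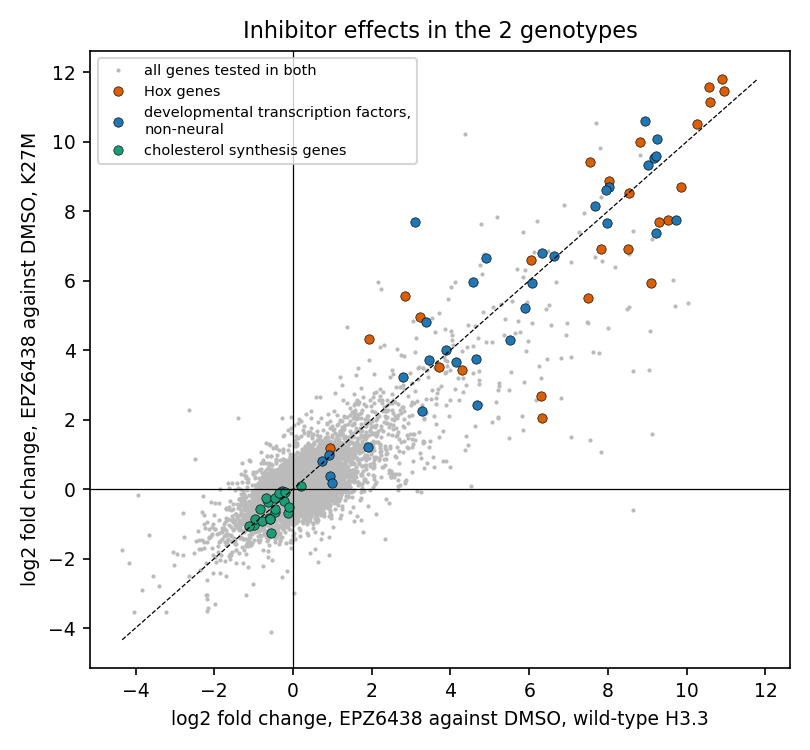
Log2 fold change under the inhibitor in wild-type H3.3 cells (horizontal axis) and K27M cells (vertical axis), a point per gene tested in both, with Hox genes, developmental transcription factors outside the neural lineage and cholesterol synthesis genes in colour and the dashed line of equal change. Points lie along the line with r = 0.801, which includes genes with 0 counts in DMSO that could only rise. Fitted values of those genes depend on the prior count and are no bounds.

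The K27M effect and the inhibitor effect in wild-type cells share the wild-type DMSO libraries. Among 12660 genes 1450 rose in both and 1773 fell in both, where independent lists would share 766 and 839. Another 459 were called in opposite directions. The fold changes had a Pearson r of 0.556 and a covariance of 0.235. Simulated libraries without any change, the shared ones drawn as well, gave a mean r of 0.498 and a covariance of 0.0204 over 10 simulations. Genes were drawn independently, so the simulations lack the GC-linked deviations of the real libraries and may understate what shared controls produce. With GC trends removed 1198 rose and 1390 fell in both, and 571 were opposite. The r of 0.488 then lay below the simulated 0.506, and the covariance was 0.148 against 0.0177. Col11a1 and Cdkn1c rose in both and Lfng fell in both, while Cdkn2a fell with K27M and rose with the inhibitor. The count of shared calls was 5693, 1942 and 1568 without wild-type DMSO replicates 1, 2 and 3, and 2101 and 1924 without wild-type inhibitor replicates 1 and 3. For the K27M effect and the reversed inhibitor effect in K27M cells, which share the K27M DMSO libraries, 1716 and 1697 of 13040 genes were shared and 1354 were opposite, where independent lists would share 1105 and 1093. The covariance was 0.088, against 0.0216 simulated, with an r of 0.236 against 0.472. With GC trends removed 1128 and 1106 were shared and 1454 were opposite, with a covariance of 0.0431 against 0.0183 and an r of 0.152 against 0.475. The count was 2209 and 2121 shared calls without K27M DMSO replicates 1 and 2. With 3 libraries the shared controls cannot be split, so part of either overlap may come from them.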

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

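Of the tests below, the comparison of replicate spread, both tests of Cdkn2a and the values with GC content corrected, with a block or with the transcripts of any table were chosen only after the result was seen, while the bounds for the GC and depth tests of the first 2 patterns were set before their values were seen. All values in the first 3 paragraphs differ in the inhibitor response between genotypes by the test of that difference over 12 libraries, on the log2 scale, where a positive value is a higher response in K27M cells.

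The response differed for 4662 genes, 2606 higher and 2056 lower, while at least 2-fold differences were 160 higher and 391 lower. By construction this difference is also the genotype effect under the inhibitor minus the genotype effect in DMSO. The genotype log2 fold changes had an SD of 0.241 under the inhibitor and 0.587 in DMSO. Much of this result therefore restates the DMSO difference between genotypes with its sign turned, and is not separate evidence. With GC content corrected 2811 genes differed, and 40.6% of the 4662 calls were kept in the same direction. Among cell cycle inhibitors it was higher for Cdkn2a (2.01) and Cdkn1a (0.68, or 0.42 with GC content corrected) and lower for Cdkn1c (-1.43) and Cdkn1b (-0.73, or -0.35 with GC content corrected). Cdkn1c went from 4.47 ± 0.786 to 21.7 ± 1.90 CPM in wild-type and from 9.60 ± 0.352 to 17.6 ± 2.13 CPM in K27M cells (SD, n = 3). Of p53 targets Phlda3, a repressor of AKT signalling, responded higher (0.85, or 0.40 with GC content corrected) and Btg2 (-0.64) and Perp (-0.80) lower. Perp did not pass with the replicate number as a block and GC content corrected. Ezh2 (-0.62) and Jarid2 (-0.72) were lower, and the PRC2 subunits had a median of -0.37, a list call lost with an estimated correlation (adjusted p = 0.314). With GC content corrected Ezh2 stood at -0.23 and the PRC2 median at -0.15, and the PRC2 list did not pass (adjusted p = 0.111).

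In the HoxA cluster Hoxa5 (2.74) and Hoxa4 (2.40) responded higher and Hoxa10 (-4.28) lower. Hoxa10 rose in both genotypes, from 0.105 to 11.7 CPM in wild-type and from 1.37 to 7.35 CPM in K27M cells. Its fitted difference rests on few counts in wild-type DMSO libraries. Hoxa9 had 3 counts in wild-type DMSO and 65 in K27M DMSO libraries (ratio 12.5, interval 4.1 to 62.4), so its fitted difference (-4.34) depends on the prior count. Levels under the inhibitor were close between genotypes for Hoxa5, at 60.1 ± 4.66 and 56.8 ± 2.33 CPM, and its DMSO levels were 8.60 ± 0.513 and 1.21 ± 0.0837 CPM. Pax9 responded higher (6.37), a fitted value that depends on the prior count because K27M DMSO libraries had 0 counts. Among glial genes Gfap (-1.48), Aqp4 (-2.18), Hes5 (-0.75), Pdgfra, the PDGF receptor of precursors (-0.78), Gpr17 (-1.31), Ugt8a (-2.65) and Tspan2 (-2.04) responded lower, while Aldoc (0.78), S100b (0.71) and Lfng (0.62) responded higher. With GC content corrected Lfng stood at 0.24 and Hes5 at -1.21. Of 8 mature oligodendrocyte markers 3 responded lower and 1 higher (median -0.41), a list call lost with an estimated correlation (adjusted p = 0.239), with GC content corrected (adjusted p = 0.0553) and without wild-type DMSO replicate 1 (adjusted p = 0.295). Shh responded lower (-0.97).

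Further genes with a higher response were Entpd5, an ectonucleotidase family gene (4.25), Gpd1 (1.69), Psd (1.59), the transcriptional corepressor gene Tle6 (1.27) and Phlda1 (1.21). Lower were the protocadherin gene Pcdh17 (-2.19), Col11a1 (-2.16), Fndc3c1 (-1.99), Apcdd1 (-1.93), Igsf10 (-1.91) and Anks1b (-1.68). Grb10, an imprinted adaptor of insulin signalling chosen after its values were seen, responded lower (-2.85): it went from 5.39 ± 0.268 to 38.2 ± 1.83 CPM in wild-type cells and stayed at 47.2 ± 1.3 and 46.3 ± 3.29 CPM in K27M cells. With the transcripts of any table counted, the value was 0.43 for Entpd5, -3.64 for Hoxa10, -1.30 for Igsf10, 4.52 for Pax9 and -2.64 for Grb10. The value of 4.25 for Entpd5 therefore rests on counting only its transcripts listed in all 4 tables. Of 100 splits the real one alone called as many as 4662 genes, and the highest other split called 2865 genes. The other splits mixed treated and untreated libraries within a genotype, so the inhibitor effect added to their spread. They do not stand for libraries with equal responses, so chance is not excluded by them.

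The first pattern is the 7897 genes called between K27M and wild-type cells in DMSO. Greater depth of the K27M DMSO libraries is argued against, since 6674 genes were called with all libraries thinned to the smallest. Thinning came after transcripts were listed, so it does not test whether depth shaped which genes were listed. A GC-dependent bias between libraries remains open: with each library's GC trend removed 47.3% of the calls were kept in the same direction, between the bounds of 20 and 50% set for that test. Part of these calls may therefore come from library composition, and an effect of K27M, which the groups name, stays open beside it. Cdkn2a and Hoxa5 kept their calls after the correction, at -1.71 and -2.79.

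The second pattern is the small number of genes called between genotypes under the inhibitor, 234. The fit with the replicate number as a block, given below, called more genes. Whether the replicates pair stays undecided, and the tests of this pattern used the fit without the block. Lower depth of the inhibitor libraries is argued against, since after thinning the DMSO comparison called 39.7 times as many genes (6674 against 168). A larger spread between replicates is argued against by the common dispersion of 0.005826, against 0.01167 in DMSO. With GC trends removed the ratio was 7.7 (5616 against 727), so a GC-dependent bias could account for part of the contrast. A candidate explanation is that EZH2 inhibition brings the genotypes to similar expression, which stays a hypothesis.

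The third pattern is the lower Cdkn2a in K27M cells in DMSO. A GC-dependent bias is argued against by a log2 fold change of -1.71 (SE 0.06, adjusted p = 1.84e-05) with the trend removed. Loss of the locus in K27M cells is argued against by the level under the inhibitor, where the genotypes differed by -0.10 (SE 0.085, adjusted p = 0.608). Repression of Cdkn2a that needs EZH2 activity in K27M cells is a candidate explanation, found and tested on the same libraries, and other differences between the cultures stay open.

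In each pair of groups the real split was 1 of 10 splits, too few for a share under 0.05. The real splits called 7897, 5420, 7599 and 234 genes and the highest other split 0 in each.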

How the results depend on the processing

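Chosen after seeing the data were the GC and length corrections (also with a block), thinning, the estimated correlation, fry, leaving out libraries in overlaps and list tests, and for the difference DESeq2, Bonferroni, the block and leaving out libraries. Of named genes called with or without a change of setting, the direction reversed for Egfr (-0.05) and Pdgfra (-0.06) in DMSO with GC content and length corrected, and H3f3b for the inhibitor in wild-type cells with GC content corrected (-0.02; -0.01 with a block) and for the difference with both (0.47). Uncalled genes also changed sign with GC content corrected: Cdkn2b in DMSO (0.17), Ezh2 for the inhibitor in wild-type cells (-0.05), and for the difference Eed (0.05) and H3f3b (0.48). H3f3a and Grb10 values near 0 did so under other settings. DESeq2 called 7075, 5017, 6413, 259 and 4711 genes in the order K27M in DMSO, inhibitor in wild-type cells, inhibitor in K27M cells, genotypes under the inhibitor, and difference. In that order, Bonferroni adjustment gave 95, 366, 1669, 11 and 175 calls. An adjusted p threshold of 0.01 gave 3964, 2907, 39 and 1954, the inhibitor in K27M cells apart, and a threshold of 0.10 gave 470 under the inhibitor. At least 2-fold changes numbered 1033, 1274, 1248 and 16 in the pairs of groups, of which 85%, 74.9%, 73.6% and 56.2% were higher, against 49.5%, 50.8%, 51.4% and 31.6% of all calls. None of these 2-fold counts was repeated with GC content corrected. Genes at or above the median abundance gave 4883, 3129 and 4317 calls, as fewer were tested. GC correction gave 727 calls under the inhibitor and 2811 for the difference, with length 930 and 2749, with a block 5194 in DMSO and 814 under the inhibitor, and a block alone 539 there. The authors' tables gave 1504, 1212, 2366 and 64 transcripts with Bonferroni, and 13450, 9267, 12159 and 2460 with unshrunk errors. Per gene, they gave 4804, 3260 and 4375 by the most abundant transcript, 3583 and 4911 by any called transcript in the inhibitor comparisons, and 4951 with a Sidak correction in K27M cells. For the difference they gave 2341 and 2382 transcripts. Shared inhibitor calls were 2045 at 0.01 and 1790 by the most abundant transcript, those of K27M and inhibitor effects 1163 and 1820, and those with the reversed effect 1622, 1643 and, with GC content corrected, 2234. Passing lists numbered 18 with a preset correlation of 0.05, 4 with an estimated correlation and 65 with fry, against 30. Of the 30 list calls, 14 were kept and 16 lost with the effect alone as the statistic, 22 kept and 8 lost with its ranks, and 27 kept and 3 lost with GC content corrected. Leaving out a library gave 5026 to 9279, 3344 to 7702, 6626 to 7681, 17 to 195 and 3238 to 6821 calls, 2453 to 3408, 1568 to 5693 and 2121 to 3750 shared calls, and 26 to 32 lists. The replicate numbers were not taken to pair the libraries, as the rule asked for a correlation above 0.1 in every pair of the same number: 11 of 18 had it (r from -0.22 to 0.76). As a hint from the data, 7 of 12 libraries correlated best with their own number, so whether they pair stays undecided. Where construction does not show it, the cause was not tested. With the deposited scaled values in place of the undone counts, 216 results of named genes stayed the same and 3 lost their call. Other alternatives for normalized values were not run, since the tables hold counts. At these depths a 2-fold change was recovered for 50, 49, 50, 50 and 43 of 50 simulated genes above the median abundance.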

Other observations

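No artifact test is reported in this part, and the corrected values in it were chosen after the result was seen. Among genes outside the lists, the inhibitor lowered Agt, the precursor of angiotensin that astrocytes secrete, from 61.6 ± 5.57 to 11.9 ± 0.208 CPM in wild-type and from 59.1 ± 3.37 to 11.8 ± 1.57 CPM in K27M cells (SD, n = 3). Cd109, a surface antigen that restrains TGF-beta signalling, fell by 2.40 on the log2 scale in K27M cells, and Rab3b, a vesicle trafficking gene, fell by 2.32 in wild-type cells. The matrix gene Hmcn1 rose 6.09-fold in wild-type cells and the matrilin gene Matn2 4.83-fold in K27M cells. Under the inhibitor Nes, the filament gene of neural progenitors, was 1.16-fold higher and Sox2, a stem cell factor, 1.18-fold lower in K27M than in wild-type cells. The called p53 targets that rose there were Mdm2, the p53 ubiquitin ligase (1.17-fold), and Plk2 (1.15-fold), and the stress list's called member was Hspa5, the chaperone of the endoplasmic reticulum (1.20-fold). These 5 calls under the inhibitor did not hold without single libraries: the adjusted p without wild-type replicate 3 or K27M replicate 1, 2 or 3 was 0.0967, 0.107, 0.136 and 0.163 for Nes, 0.136, 0.150, 0.121 and 0.181 for Sox2 and 0.0964, 0.0808, 0.106 and 0.128 for Hspa5. Mdm2 and Plk2 lost their calls without any of the 6 libraries (up to 0.228 and 0.233).

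Across all 12 libraries the first principal component of 10222 genes held 55.7% of the variance and the second 31.6%. Within groups the main axis of variation held 70.1% of the variance and followed GC content with an absolute Spearman correlation of 0.82 across 8865 genes, which are not independent replicates. Wild-type DMSO replicate 1 deviated from its group with an SD of 0.242 on the log2 scale.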
